A study of Triticum aestivum and Triticum turgidum subsp. durum and Aegilops tauschii with 4 samples.

How the data were processed

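Small RNA tags were analysed in 4 libraries, 1 for each of the BBAA parent, the DD parent, their BAD hybrid and the BBAADD polyploid. Per the labels, total RNA came from 2 g of tiller tissue of 2-month-old plants, pooled from 6 plants for each parent and the polyploid and from 3 plants for the hybrid. RNA of 18 to 32 nt was size selected before adapters were ligated. The DD parent's seeds were vernalised for 3 to 6 weeks at 4 °C, and all plants grew at 20 °C under short days.

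Each file deposited by the authors lists distinct sequence tags with a whole number of reads, so the unit is a raw read count that was not normalised. Large counts carry a comma as separator, which was removed. Tags were already trimmed of the 3′ adapter. The longest trimmed tags were 28 nt in the parents and the hybrid and 26 nt in the polyploid, beside a class of untrimmed reads of 35 nt in the former and 33 nt in the latter. The trimming tool, the read length and any filter are not stated in the labels.

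Reads of 18 to 30 nt were counted and expressed per 1000000 of them (RPM). A tag of 19 to 24 nt belonged to a microRNA family when it held a conserved core of that family at an offset of 0 to 3 bases, without mismatch. The families, their grouping into lists by known targets and the sequences of transposon termini, rRNA and tRNA were written from general knowledge before the data were examined. The lists were phase change, auxin, silencing machinery, copper, development, nutrient, immune receptors and kinases, other, reproductive phased RNA, and families absent from cereals as background. Names for the 5′ adapter, further families of other organisms, plastid tRNA ends, a miR397 form that starts 2 bases later and forms of 6 families found in cereals were added after the data were examined. Sequences of other organisms are given by name and count, never by sequence.

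Transposon reads were 20 to 25 nt reads that held the Stowaway or CACTA terminus on either strand, or lay within the start of the Angela/WIS2 long terminal repeat. The chance level of the Stowaway terminus came from 100 shuffles of its bases. Structural reads of at least 18 nt lay within 5S rRNA, 5.8S rRNA or listed tRNAs. Parental origin was read from exact 24 nt tags after each library was thinned to 636349 reads of that length with a fixed seed. Mixes of the parents' own reads at 2 to 1 and 1 to 1 were made from reads not used to define the parents' tags. They gave the level each ratio would produce if every genome yielded the same number of 24 nt reads, which was not tested. Parent-specific tags had at least 10 reads in 1 part of the parent's reads, were absent from the other parent, and were measured per 1000000 reads of 24 nt in the remaining part.

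Comparisons were hybrid over mid-parent (the unweighted mean of the parents), polyploid over mid-parent, polyploid over hybrid, and DD over BBAA. With 1 library per group, no test across samples was made and no p-value is given. Shares carry 95% Clopper-Pearson intervals, ratios of a pair of libraries carry exact conditional binomial intervals, and ratios to the mid-parent carry delta-method intervals on Poisson counts. Intervals and floors cover counting error only. A family was called higher or lower when it differed by at least 2-fold, its interval excluded 1, and it had at least 10 RPM in a compared library. A family was measured when it reached that level. A count of 0 was set to a floor of 3 reads for unlisted tags. List medians, taken over the most abundant tag of each family, were placed among 10000 random lists of unlisted 20 to 22 nt tags matched on abundance.

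The naming rule was fixed before the data were examined. It names the families of the phase change, auxin, silencing machinery and copper lists, and up to 10 families per direction with the largest ratios in each comparison. It adds up to 5 unlisted tags of 20 to 24 nt per direction with the largest ratios among those of at least 100 RPM. A named tag is printed only if it was not on the list of other organisms and adapters, reached 10 RPM in a parent and in a progeny library, and had at least 10% of its parental level in the progeny. This print rule was added after the data were examined, because an unlisted tag in a single library may come from another organism.

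Alternatives changed the length range, the count minimum, the tags left out, the mismatches allowed, the scaling, the size rule, the weight of the mid-parent, the denominator of transposon reads and the depth, and their effect is described at the end. For families, 4 other scalings were used: total microRNA reads, the median family ratio, reads of 18 to 22 nt, and reads of the same length. The polyploid's microRNA reads were also set against the number that the parents' mean microRNA share at each read length would give. The ratio intervals and the size rule were tested on simulated Poisson counts, the error model that the intervals assume. The families simulated, 17 or 18 per comparison, had at least 10 RPM in the denominator. Spread between libraries and families below that level, such as miR398 and miR408, were not covered. The intervals held the true fold in 94.5% to 95.9% of simulations, unchanged families were called in 0%, and 3-fold changes were called in 100.0%, or 99.97% in the comparisons of single libraries, and falls to 0.333 in 99.0% to 99.9%. Of 1180 synthetic family tags, 0 were assigned wrongly, and 0 of 100000 random tags were assigned. No reference genome was used here, so no tag has a position, and the table that pairs locus tags with symbols was not used. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.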

Results

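Small RNA was sequenced from vegetative wheat plants in 4 libraries: a tetraploid durum wheat (BBAA parent, cultivar Langdon TTR16), the diploid goat grass Aegilops tauschii (DD parent, TQ113), their F1 hybrid (BAD hybrid) and the hexaploid that carries both parents' genomes in doubled number (BBAADD polyploid). Each group had 1 library from a pool of plants, so no value has a replicate and no difference can be set against a spread between plants. The libraries held 6262308 reads for the BBAA parent, 3372001 for the DD parent, 5477298 for the hybrid and 2808084 for the polyploid. Of these, 6032903, 3118258, 5287603 and 2692414 reads were 18 to 30 nt long and form the base of reads per 1000000 (RPM). A count of 0 allowed up to 0.497 RPM in the BBAA parent, 0.962 in the DD parent, 0.567 in the hybrid and 1.11 in the polyploid. Intervals are 95% (Clopper-Pearson for shares) and cover counting error only.

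The polyploid library differed from the other 3 in marks of library preparation and sequencing. Its longest trimmed tag was 26 nt, against 28 nt in the others. Reads with an undetermined base made up 0.584% of it and at most 0.0242% of the others. Reads from the 5′ adapter reached 7682 RPM in it and at most 234 RPM in the others. The 100 most abundant tags took 46.6% of its reads, against 15.8% in the BBAA parent, 25.7% in the DD parent and 20.4% in the hybrid. Because only this library carries these marks, its group and its handling cannot be told apart in any comparison.

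The length of the tags separates microRNA-sized RNA of 20 to 22 nt from the 24 nt RNA of the kind that directs silencing of repeats. Tags of 24 nt made up 64.6% of the BBAA parent's reads (64.5 to 64.6), 48.4% of the DD parent's (48.4 to 48.5), 57.4% of the hybrid's (57.4 to 57.4) and 23.7% of the polyploid's (23.7 to 23.8). The hybrid's share was 1.02 times the mid-parent value of 56.5% (1.01 to 1.02), and it lay below the mean weighted by genome number, 59.2%. Among tags of at least 3 reads the hybrid's ratio fell to the other side of 1, at 0.943. The polyploid's share was 0.420 times the mid-parent value (0.419 to 0.421). The DD parent's share was 0.750 times that of the BBAA parent (0.749 to 0.751).

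Tags of 21 nt made up 14.0% of the BBAA parent's reads, 19.3% of the DD parent's, 17.7% of the hybrid's and 37.4% of the polyploid's. The polyploid exceeded the mid-parent value 2.25-fold at 21 nt (2.25 to 2.26), 2.52-fold at 20 nt (2.51 to 2.53) and 3.82-fold at 19 nt (3.79 to 3.84). Tags of 22 nt were 3.32 times as frequent in the DD parent (15.9%) as in the BBAA parent (4.78%), and the hybrid held 8.04%. At 22 nt the polyploid was at 0.866 of the mid-parent value, but at 1.68 once the 100 most abundant tags of each library were left out. The ratio of 24 nt to 21 nt reads was 4.62 in the BBAA parent, 2.51 in the DD parent, 3.24 in the hybrid and 0.634 in the polyploid. Fragments of rRNA and tRNA, which are other classes of RNA, had ratios of 0.657, 0.709, 0.607 and 0.153 in the same order. The polyploid was at 0.178 of the mid-parent ratio for all reads and at 0.224 for these fragments (0.205 to 0.243).

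**Figure D1:**
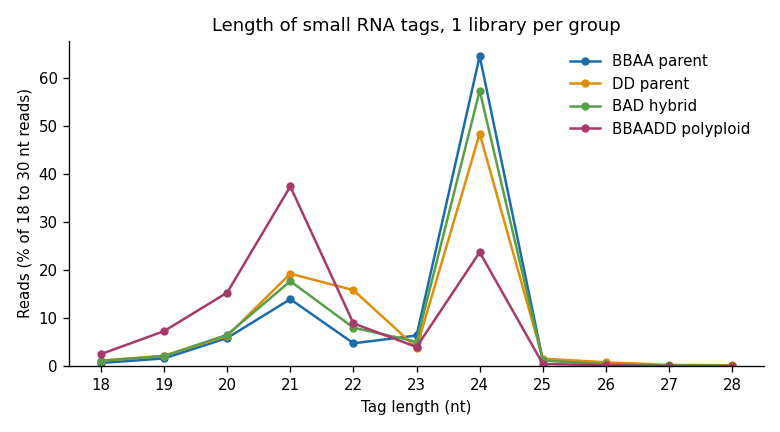
Share of 18 to 30 nt reads (percent, vertical axis) by tag length (nt, horizontal axis), with a line for each of the 4 libraries. The 24 nt class was 64.6%, 48.4% and 57.4% in the BBAA parent, DD parent and hybrid and 23.7% in the polyploid, where the 21 nt class was 37.4%.

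**Figure D2:**
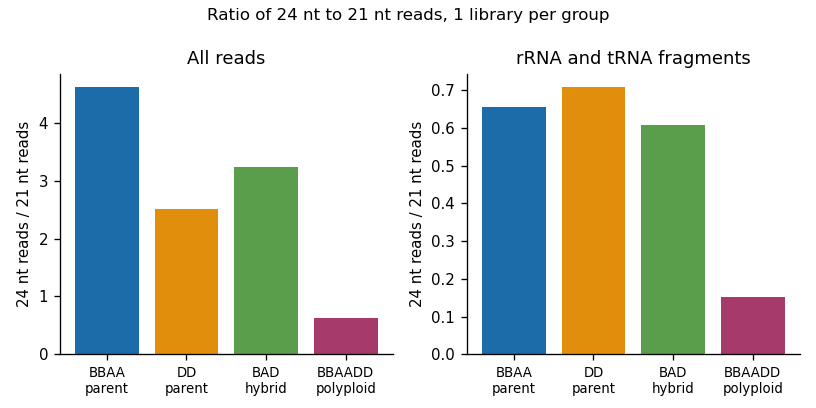
Ratio of 24 nt to 21 nt reads in each library for all reads (left) and for rRNA and tRNA fragments (right), on separate linear axes that start at 0. The polyploid bar was the lowest in both panels, at 0.634 and 0.153.

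Listed microRNA families took 10.8% of the BBAA parent's reads (10.8 to 10.8), 15.3% of the DD parent's (15.2 to 15.3), 13.0% of the hybrid's (13.0 to 13.1) and 28.2% of the polyploid's (28.1 to 28.2). The hybrid stood at 1.0004 times the mid-parent share (0.997 to 1.003), and the polyploid at 2.16 times (2.15 to 2.17). Among reads of 18 to 22 nt alone, the share was 40.0%, 33.9%, 36.6% and 39.1% in the order BBAA, DD, hybrid, polyploid, and the polyploid was at 1.06 of the mid-parent. Among reads of all lengths but 24 nt, it was 30.5%, 29.6%, 30.6% and 36.9%, and the polyploid was at 1.23 of the mid-parent (1.22 to 1.23). Without miR168 the polyploid was at 0.774 (0.771 to 0.777), with the miR168 reads kept in the denominator. Of all reads, the polyploid's share without miR168 was 13.4%, or 1.35 times the mid-parent (1.34 to 1.35). Without miR9863 instead, it was 26.4%, or 2.81 times the mid-parent (2.80 to 2.82). The family miR168, which targets the silencing protein AGO1, held 3.15% of the BBAA parent's reads, 3.09% of the DD parent's, 4.06% of the hybrid's and 14.8% of the polyploid's. The family miR156, which targets SPL factors of phase change, held 5.42%, 4.18%, 5.03% and 8.25%. The family miR9863, which targets immune receptors, held 0.582%, 6.71%, 2.16% and 1.73%.

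The hybrid was compared with the mid-parent to ask what bringing the genomes together did to microRNA levels. Of 19 measured families, 0 were called higher and 2 lower. The copper-related miR528 stood at 332.9 RPM in the hybrid against 542.5 in the BBAA parent and 930.6 in the DD parent, a ratio to the mid-parent of 0.452 (0.428 to 0.477) that stayed below 0.5 under each of 4 other scalings. The miR390 family, the trigger of auxin-related small RNA, stood at 0.466 (0.289 to 0.753), with 23 reads in the hybrid. It lost its call under 3 of those 4 scalings, at 0.522, 0.549 and 0.508, values within that interval. It also lost it over tags of at least 3 reads (0.504) and with a mid-parent weighted 2 BBAA to 1 DD as in the hybrid's genomes (0.632, 0.392 to 1.017). The largest rises were below 2-fold: 1.84 for miR396, 1.71 for miR164, 1.49 for miR166 and 1.30 for miR168. The next largest falls, also below 2-fold, were 0.591 for miR9863 and 0.824 for miR827. Each was on the same side of 1 under all 4 scalings, although miR9863 came to 0.979 (0.972 to 0.986) within reads of the same length. The auxin families miR167 (1.03), miR393 (1.12) and the phase-change families miR156 (1.05) and miR172 (0.979) were close to 1, and miR167, miR156 and miR393 changed side of 1 under other scalings. The auxin-related tasiARF was at 1.27 (1.02 to 1.58), and miR169 (1.28), miR444 (1.27), miR1432 (1.18) and miR159 (1.15) were also above 1, while miR5048 (0.937) was below 1 except within reads of the same length. In RPM, 4 families of the hybrid (miR164, miR166, miR396 and miR168) lay above both parents and 2 (miR827 and miR528) below both, intervals included.

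The polyploid was compared with the mid-parent to ask the same of the combined and doubled genomes. Of 24 measured families, 15 were called higher and 1 lower. The families miR394, miR160, miR395, miR398 and miR408 were below 10 RPM in both parents and were measured through the polyploid alone. By total reads they could not be called lower. The median family moved by 1.61 on the log2 scale, and relative to that shift 7 families were higher and 7 lower. The copper-related miR398 had 31.6 RPM, against 1.82 in the BBAA parent and 0.321 (1 read) in the DD parent, a ratio of 29.4 (15.9 to 54.7). The ratio was 16.5 for miR394 (11.5 to 23.6), 12.0 for the copper-related miR408 (6.16 to 23.2; 0 reads in the DD parent), 10.1 for miR396 (9.83 to 10.4), 8.73 for miR159 (8.36 to 9.12), 6.93 for the auxin family miR160 (5.03 to 9.55) and 6.19 for miR171 (4.77 to 8.03). These 7 families were called higher under all 4 other scalings. Within reads of the same length, miR444 (4.92) and miR168 (4.74) were also called, at 2.17 and 2.06, but relative to the median they were not. The ratios of 4.42 for miR164, 4.12 for miR172 and 3.53 for miR395 fell below 2-fold under each other scaling. Those of 2.62 for miR393, 2.47 for miR169 and 2.45 for miR528 changed direction relative to the median, to log2 values of -0.21, -0.30 and -0.31.

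Immune-related miR9863 was the 1 family called lower, at 0.476 (0.471 to 0.481), but it was not called within reads of the same length (0.711), with a mid-parent weighted 2 to 1 (0.661) or with 20 to 25 nt reads (0.505). The ratio of 0.872 for miR5048 was below 1 under every scaling, and it was called lower by microRNA reads (0.414), by the median (0.287) and by 18 to 22 nt reads (0.445). The ratios of miR156 (1.72), miR167 (1.42), miR390 (1.27), miR166 (1.102) and tasiARF (1.95) were below 2-fold and all changed direction within reads of the same length, where tasiARF stood at -0.02 on the log2 scale and miR167 nearer still to 0. Of these, miR166 was called lower under each of the 4 other scalings, at 0.479 by microRNA reads, 0.362 by the median, 0.494 by 18 to 22 nt reads and 0.464 within the same length. In RPM, 19 families of the polyploid lay above both parents and 0 below both. The family miR158, which cereals lack, had 254 RPM in the polyploid and at most 1.92 in the other libraries, so families with the same form in both kinds of plant cannot be assigned to wheat alone there.

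**Figure D3:**
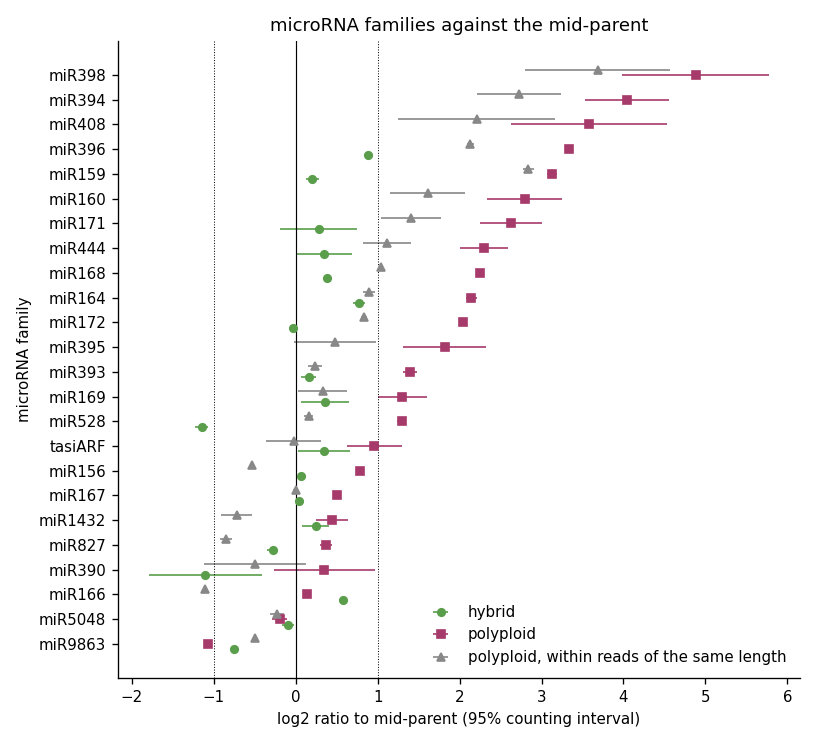
Log2 ratio to the mid-parent (horizontal axis, bars are 95% counting intervals, dotted lines mark 2-fold) for 24 microRNA families in the polyploid, 19 of them also in the hybrid, with the polyploid's values within reads of the same length as triangles. In the polyploid 15 families lay above the upper dotted line by total reads and 9 of those within reads of the same length, where miR156, miR166, miR390, miR827, miR1432, miR167 and tasiARF changed direction.

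The polyploid was compared with the hybrid because both carry the same 3 genomes and differ in copy number. Of 24 families, 15 were called higher and 0 lower, with a median shift of 1.52 on the log2 scale. Relative to that shift 4 were higher and 5 lower. The families miR394, miR160, miR390, miR395, miR398 and miR408 had less than 10 RPM in the hybrid, so by total reads they could not be called lower. The ratio was 62.8 for miR408 (10.5 to 2559, with 1 read in the hybrid), 41.7 for miR398 (15.7 to 156.7), 9.32 for miR394 (6.57 to 13.5) and 7.58 for miR159 (7.22 to 7.95), and these 4 were called under every scaling. The ratio of 5.50 for miR396 (5.35 to 5.65) and 5.43 for miR528 (5.14 to 5.73) came to 1.92 and 1.90 relative to the median. Other called ratios were 5.09 for miR171, 4.65 for miR160, 4.21 for miR172, 3.86 for miR444, 3.64 for miR168 and 2.99 for miR395. Of these, miR171 and miR160 lost the call by the median alone, miR172 under 3 of the 4 other scalings, and miR444 (1.35 to 1.92), miR168 (1.27 to 1.81) and miR395 (1.05 to 1.49) under all 4. Those of 2.73 for miR390, 2.59 for miR164 and 2.35 for miR393 changed direction relative to the median. The family miR166 was at 0.739 (0.725 to 0.752) and was called lower under each of the 4 other scalings. The ratios of 0.805 for miR9863 and 0.931 for miR5048 were below 1 under every scaling. By microRNA reads, by the median and by 18 to 22 nt reads both were called lower, miR9863 at 0.373, 0.281 and 0.400 and miR5048 at 0.432, 0.326 and 0.463. Those of 1.64 for miR156, 1.53 for tasiARF and 1.38 for miR167 changed direction under at least 3 of the 4 other scalings.

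The parents were compared to describe the difference from which the hybrid started. Per the labels only the DD parent's seeds were vernalised, so genome and this treatment cannot be told apart here or in the mid-parent. Of 19 families, 4 were called higher in the DD parent and 0 lower, with a median shift of -0.01 on the log2 scale. Among these 19, by 18 to 22 nt reads 3 were higher and 6 lower (miR156, miR164, miR166, miR167, miR171 and miR827), and by microRNA reads or within reads of the same length 3 were lower (miR164, miR166 and miR167). The families miR390 (1.99 RPM) and miR169 (9.28 RPM) were below 10 RPM in the BBAA parent and were measured through the DD parent alone. By total reads they could not be called lower. The family miR171 (8.66 RPM in the DD parent) was measured through the BBAA parent alone and could not be called higher. By total reads the ratio was 11.5 for miR9863 (11.4 to 11.6), 8.38 for miR390 (4.42 to 17.3), 4.87 for miR169 (3.55 to 6.76) and 2.33 for tasiARF (1.72 to 3.16). The first 3 were called under all 4 other scalings, with miR9863 at 3.51 (3.47 to 3.55) within reads of the same length, and tasiARF was called under 1 of them. The lowest ratio was 0.536 for miR167 (0.523 to 0.548), which was called lower by 3 of the 4 other scalings. The phase-change families miR156 (0.771) and miR172 (0.933) and miR168 (0.980) were below 1 under every scaling, as were miR164 (0.630), miR166 (0.668) and miR827 (0.826). The ratios of 1.75 for miR159 and 1.72 for miR528 were above 1 under every scaling, and those of 1.91 for miR5048, 1.47 for miR393 and 1.17 for miR396 changed direction under at least 1.

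Some listed families were not measured. No reads of miR529 were found in any library, and miR535, miR162 and miR397 had at most 5 reads in any library. A miR397 form that starts 2 bases later had 254.9 RPM in the BBAA parent, 0 in the DD parent, 29.9 in the hybrid and 1611 in the polyploid. The reproductive families miR2118 and miR2275 had 0 reads and 1 read over the 4 libraries, so these families gave no sign of inflorescence tissue at this depth. Other marks of that tissue were not examined.

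Medians of the lists were placed among 10000 random lists of unlisted tags of 20 to 22 nt and like abundance. The lists differ in size and between comparisons. The families miR394 (development), miR160 (auxin), miR395 (nutrient), and miR398 and miR408 (copper) reached 10 RPM in the polyploid alone. This by itself favours high ratios in the polyploid's comparisons. In the polyploid's comparisons, development held 8 families, auxin 5, copper 3, nutrient, phase change and immune receptors and kinases 2 each, and silencing machinery and other 1 each. In the hybrid over the mid-parent, development held 7, auxin 4, phase change and immune receptors and kinases 2 each, and copper (miR528), nutrient, silencing machinery and other 1 each, so these last are values of a single family. For the polyploid over the mid-parent, the percentile was 98.9 for all families, 99.7 for development, 95.6 for copper, 80.0 for silencing machinery, 77.6 for phase change, 63.9 for nutrient, 52.1 for auxin, 48.8 for other and 24.9 for immune receptors and kinases. For the hybrid over the mid-parent, it was 98.0 for development, 84.6 for all families, 72.8 for silencing machinery, 64.6 for other, 63.4 for phase change, 61.6 for auxin, 46.1 for nutrient, 30.5 for immune receptors and kinases and 8.62 for copper. For the polyploid over the hybrid, copper (99.8), development (99.5) and all families (97.5) were the highest. For DD over BBAA, all families stood at 0.05, since unlisted tags of like abundance had a median log2 ratio of 2.08 and the families one of 0.16.

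Unlisted tags separated the parents. Of rRNA, only 5S and 5.8S were listed, so fragments of other rRNA can be among the unlisted tags. The 21 nt tag TACGGCATATTAATATCTCTA had 4286 RPM in the DD parent and 3 reads in the BBAA parent, a ratio of 8619 (2949 to 41800), and reached 1626 RPM in the hybrid and 591.7 in the polyploid. The tag TTTTCGGCATCATATTATCAT was at least 2433-fold higher in the DD parent (1210 RPM) than in the BBAA parent. The 22 nt tag CGGTTGGGCTGTATGATGGCGA had 1827 RPM in the BBAA parent, was at least 1899-fold lower in the DD parent, and had 1016 RPM in the hybrid and 2022 in the polyploid. The tag AAGGAACTGATGGTATTGCAT had 1076 RPM in the BBAA parent, 0 in the DD parent, 713.2 in the hybrid and 779.2 in the polyploid. Against the mid-parent, the hybrid was highest for ATTTATTTCAAGCTATTTCGGATC, with 506.3 RPM against 168.6 in the BBAA parent and 0 in the DD parent. The tag AAACTGCGAATGGCTCATTAA had 299.4 RPM in the hybrid, 518.5 in the polyploid, and 67.0 and 69.3 in the BBAA and DD parents. Against the hybrid, the polyploid was lowest for GGAGGAACAAGATTGTTTTGGACA, at 2.23 RPM against 147.5, a ratio of 0.0151 (0.00553 to 0.0330). The tag AGGACTTAGATGTGCAATACTTAT had 3.71 RPM in the polyploid and 150.2 in the hybrid, 170.9 in the BBAA parent and 112.2 in the DD parent. Of the tags that the rule selected as highest in the polyploid, all but 1 were from the 5′ adapter. The tags selected as lowest against the mid-parent, in the hybrid and in the polyploid, had 106.1 to 5304 RPM in the DD parent and at most 83.4 in the BBAA parent. Some were forms of the animal microRNA miR-1, and none is given by sequence because its organism was not established.

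The parental origin of 24 nt reads was examined to see whether the parents' repeat-directed RNA persisted in the progeny. Of the hybrid's 24 nt reads at equal depth, 15.3% had a tag found in the BBAA parent alone, 9.09% in the DD parent alone, 7.39% in both and 68.2% in neither. For the polyploid the shares were 12.4%, 6.99%, 5.04% and 75.6%. Parents mixed at 2 BBAA to 1 DD gave 15.6%, 9.76%, 6.31% and 68.3%. A second draw of the BBAA parent's own reads left 70.2% in neither class of parental tags, and one of the DD parent's left 64.7%. Among reads found in a single parent, the DD share was 37.3% in the hybrid (37.1 to 37.6) and 36.1% in the polyploid (35.8 to 36.4). It was 38.5% in the mix of 2 to 1 and 53.8% in the mix of 1 to 1. Sequencing errors would move reads to the class of neither parent, which was not tested. A-to-C changes of the main miR168 tag came to 4.92% of exact reads in the polyploid and at most 1.07% in the others. Over every 1-base change, the polyploid was highest for miR168 (8.97%), but the DD parent was highest for miR156 (13.1%) and miR9863 (10.6%).

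Abundant parent-specific 24 nt tags were followed into the progeny, with levels per 1000000 reads of 24 nt, so the lower 24 nt share of the polyploid does not enter them. The 1748 BBAA-specific tags were at 67.4% of their parental level in the hybrid (66.5 to 68.3) and 44.5% in the polyploid (43.5 to 45.5), where 66.7% of the genomes come from that parent. The 2176 DD-specific tags were at 25.8% in the hybrid (25.5 to 26.2) and 14.9% in the polyploid (14.5 to 15.4), where 33.3% of the genomes come from the DD parent. Tags of other organisms were not left out of these sets and would lower the levels. A 24 nt tag with 2014 reads in the DD parent had 0 in every other library. Without the 10 most abundant DD-specific tags the levels were 26.1% in the hybrid and 15.5% in the polyploid. The 406 shared tags were at 116.8% in the hybrid and 73.1% in the polyploid. Tags were matched exactly, so errors in the reads of a progeny library would lower its level for each class of tag. These levels are sums over tags, and the median tag was lower, at 63.2% in the hybrid and 27.9% in the polyploid for BBAA-specific tags and at 24.9% and 7.91% for DD-specific tags. At equal depth, 95.9% of the BBAA-specific tags were seen in the hybrid and 82.6% in the polyploid, against 82.0% and 60.8% of the DD-specific tags.

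**Figure D4:**
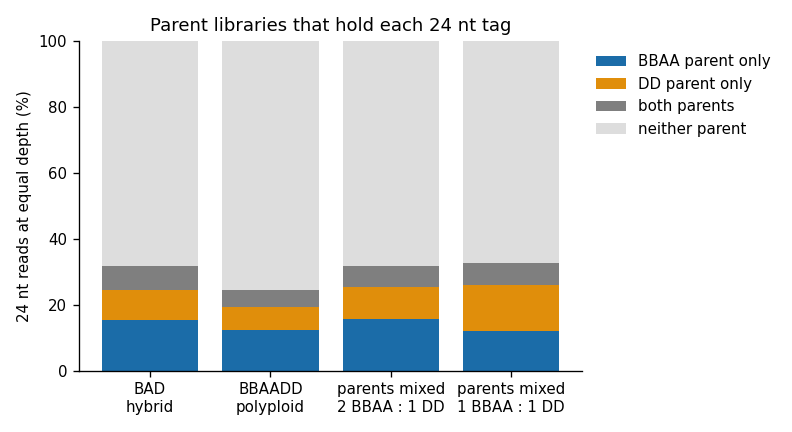
Share of 24 nt reads (percent, vertical axis) by the parent library that held the same tag, at equal depth, for the hybrid, the polyploid and mixes of the parents' own reads. The polyploid had 75.6% of its reads in neither parent, against 68.2% in the hybrid and 68.3% in the mix of 2 to 1.

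Transposon termini were counted as a measure of repeat-derived RNA. Reads with the CACTA terminus stood at 3236 RPM in the BBAA parent, 3416 in the DD parent, 3735 in the hybrid and 633.3 in the polyploid. The hybrid was at 1.12 of the mid-parent (1.103 to 1.14) and the polyploid at 0.190 (0.181 to 0.200). Per 1000000 reads of 24 nt, the values were 4244, 6265, 5600 and 1863, and the polyploid was at 0.354 of the mid-parent (0.334 to 0.376). Reads with the Stowaway terminus stood at 1259 RPM in the BBAA parent, 437.1 in the DD parent, 735.1 in the hybrid and 442.4 in the polyploid, where 100 shuffles of its bases gave medians of 13.6, 7.70, 8.61 and 4.64 RPM and highest values of 304.7, 148.8, 175.9 and 63.5. The hybrid was at 0.867 of the mid-parent (0.834 to 0.9004). The polyploid was at 0.522 (0.491 to 0.554) by all reads, at 0.892 within 24 nt reads, and at 1.31 when reads of 20 to 25 nt were set over 24 nt reads. The Angela/WIS2 repeat start had at most 3 reads in each library, so no difference was detectable at this depth.

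**Figure D5:**
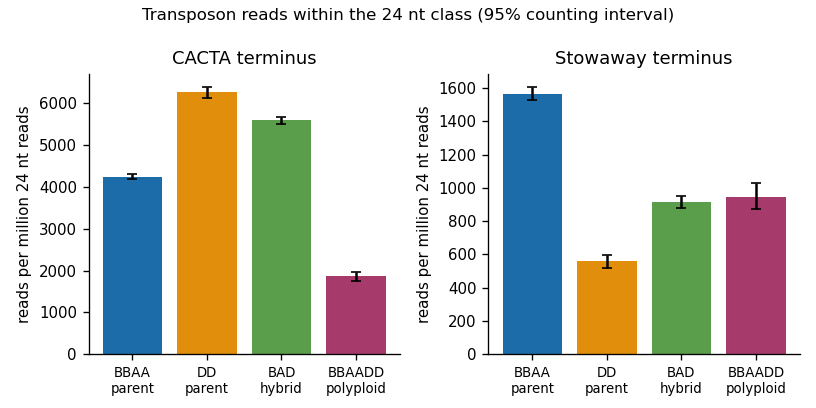
Reads per 1000000 reads of 24 nt with the CACTA terminus (left) and the Stowaway terminus (right) in each library, as bars from 0 with 95% counting intervals. CACTA reads were 4244, 6265 and 5600 in the BBAA parent, DD parent and hybrid and 1863 in the polyploid, and Stowaway reads were 914.6 in the hybrid and 947.7 in the polyploid.

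Fragments of 5S and 5.8S rRNA and of listed tRNAs together stood at 3619 RPM in the BBAA parent, 8669 in the DD parent, 7139 in the hybrid and 11929 in the polyploid. The hybrid was at 1.16 of the mid-parent (1.15 to 1.18) and the polyploid at 1.94 (1.91 to 1.97). The DD parent exceeded the BBAA parent 2.40-fold (2.35 to 2.44). The 5′ ends of plastid tRNAs took 1.49% of the BBAA parent's reads, 1.15% of the DD parent's, 1.45% of the hybrid's and 8.37% of the polyploid's.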

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

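The tests of this part on the microRNA share by read length, on single families, on forms found in cereals, on miR158 and on vertebrate families were chosen only after the result was seen.

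The family miR528 stood out because the progeny moved opposite ways from the mid-parent, to 0.452 in the hybrid and 2.45 in the polyploid. Each group is 1 library, so the difference was not tested. The polyploid's value fell below 2-fold by microRNA reads (1.15), by 18 to 22 nt reads (1.23) and within reads of the same length (1.12), and reversed relative to the median family (log2 -0.31), while the hybrid's stayed below 0.5 under all 4 scalings.

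Reads of other organisms and of adapters lie outside the comparisons and stood out by their level. In the DD parent, the animal microRNA miR-1 had 7232 RPM, against 119.7 in the BBAA parent, 164.0 in the hybrid and 26.7 in the polyploid, and miR-184 had 109.0 RPM against at most 4.31. Listed vertebrate microRNAs were 2.12 times as high in the DD as in the BBAA parent (1.36 to 3.30), far less than the 60.4-fold of miR-1, and invertebrate ones were 39.0 times as high (21.9 to 76.6). The DD library also had the highest share of untrimmed reads, 7.53%, against 4.12% in the polyploid, 3.66% in the BBAA parent and 3.46% in the hybrid. In the polyploid, the Brassicaceae family miR158 had 254 RPM, the vertebrate miR-103 had 176.4, the animal let-7 had 130.0 and the 5′ adapter had 7682 RPM. In the other libraries these reached at most 1.92, 11.2, 26.9 and 234.4 RPM. Other families listed as absent from cereals were lower: miR-21 had 20.1 RPM in the polyploid, miR173 had 1.49, miR403 had 1.11 and miR-122 at most 0.641 in any library.

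The signal of miR158 bears on the higher microRNA share of the polyploid, 28.2% against a mid-parent of 13.0%. A lower 24 nt share and a wider shift to shorter reads were argued against as the whole cause for miR168 and for single families. Outside 24 nt, miR168 was at 2.61 of the mid-parent. It was at 2.05 times the number that the parents' shares at each length give (2.04 to 2.06). At equal length, 9 of 24 families were 2-fold or more above the mid-parent and 1 (miR166) below it. Of the 9, miR394, miR160, miR398 and miR408 had reached 10 RPM in the polyploid alone, which by itself favours a rise. The total was at 1.23 outside 24 nt, 1.15 at equal length and 1.06 among 18 to 22 nt reads. Without miR168 the first of these values came to 0.774 and the next to 0.770. Reads of miR168 stayed in the denominators, which lowers both values. Outside 24 nt they made up 19.4% of the polyploid's reads, 8.88% of the BBAA parent's and 5.98% of the DD parent's. Both values also include miR9863, which was at 6.71% of the DD parent's reads and 1.73% of the polyploid's. As a share of all these reads, no rise was left in the other families together, and the shift stays open for them. RNA of a Brassicaceae-type plant was argued against as the whole cause by the forms found in cereals, 2-fold or more higher in 5 of 6 families by total reads. A shift to shorter reads would raise these too. In the polyploid, the cereal form of miR168 had 147771 RPM and the other listed form had 63.9. For miR159 these values were 2948 and 8.54 RPM, and for miR398 they were 31.6 and 1.86. Reads of the other form were thus a small part of miR168 and miR159. Of the 5 families, 4 were called higher under 3 other scalings and 2 (miR398 and miR159) relative to the median. The miR408 family is not among the 5 because its cereal form had 0 reads. Its other listed form also had 0 reads in every library, so miR408 does not bear on this origin. As a family it was called higher under all 4 other scalings. For families with the same form in both plants, the wheat and foreign parts cannot be told apart, because the 254 RPM of miR158 does not give the amount of the others, and the doubled genome stays open and untested, as does the separate handling of this library.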

How the results depend on the processing

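The alternatives of 18 to 26 nt, of leaving out adapter, other-organism and undetermined-base tags, of adding untrimmed reads, of scaling by 18 to 22 nt reads or within the same length, of 24 nt transposon reads per 24 nt reads, of plastid tRNA ends, of random tags of the same length, and of leaving listed tags out of the origin were chosen only after the result was seen. No paired analysis was possible because each group has one library. The Angela/WIS2 repeat had too few reads for a ratio under any alternative. Of the main results, 99 values stayed within their counting interval or, for counts, within 1.5-fold, 83 moved beyond it and 2 reversed; of all others 898, 740 and 14 did so. A change of sign was counted as reversed for called values only, and uncalled families that changed sign are among those that moved or stayed. The cause of a change was not tested unless given. At this depth the counting intervals are narrow, and many moves are small.

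The 24 nt share over the mid-parent was 1.02 in the hybrid and 0.420 in the polyploid. With 20 to 25 nt reads it was 1.02 and 0.450. Without 5′ adapter, other-organism and undetermined-base tags it was 1.01 and 0.422, with untrimmed reads added 1.04 and 0.426, and over distinct tags 1.03 and 0.789. In the polyploid it was 0.423 without rRNA, tRNA and adapter tags, 0.419 with 18 to 26 nt reads and 0.630 without the 100 most abundant tags. Over tags of at least 3 reads the hybrid reversed to 0.943 and the polyploid stood at 0.144, and the 22 nt share of the polyploid over the hybrid reversed to 0.802. The 21 nt share of the hybrid over the mid-parent reversed to 0.937 over distinct tags and 0.990 without the 100 most abundant tags, and the 22 nt share of the polyploid to 1.63 and 1.68.

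The microRNA share over the mid-parent was 1.0004 in the hybrid and 2.16 in the polyploid. In the polyploid it was 2.30 with 20 to 25 nt reads, 2.17 without rRNA, tRNA and adapter tags and 2.15 with 18 to 26 nt reads. In the hybrid and the polyploid it was 1.04 and 1.66 over tags of at least 3 reads, 0.996 and 2.18 without adapter, other-organism and undetermined-base tags, 1.03 and 2.20 with untrimmed reads added, 0.985 and 2.12 with 1 mismatch, and 0.973 and 2.42 without miR156, the most abundant family.

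By total reads, 0 families were higher and 2 lower in the hybrid over the mid-parent, 15 and 1 in the polyploid over the mid-parent, 15 and 0 in the polyploid over the hybrid, and 4 and 0 in DD over BBAA. The hybrid's lower families became 1, miR528 without miR390, over tags of at least 3 reads, at 100 RPM, with a mid-parent weighted 2 to 1, and when scaled by microRNA reads, by 18 to 22 nt reads or within the same length. A rule of 1.5-fold gave 2 higher families in the hybrid. The polyploid over the mid-parent had 9 higher and 3 lower when scaled by microRNA reads, 3 lower by 18 to 22 nt reads, 9 higher within the same length, 7 and 7 by the median, 7 higher at 100 RPM, and 0 lower with 20 to 25 nt reads or a weighted mid-parent, where miR9863 stood at 0.505 and 0.661. Within the same length 1 was lower, but it was miR166 and not miR9863 (0.711). The polyploid over the hybrid had 8 higher and 3 lower by microRNA reads, 9 and 3 by 18 to 22 nt reads, 8 and 1 within the same length, 4 and 5 by the median, and 7 higher at 100 RPM. The DD parent over the BBAA parent had 7 higher and 2 lower at 1.5-fold and 1 higher at 100 RPM. Its lower families were 1 with 20 to 25 nt reads and with 1 mismatch, 3 over tags of at least 3 reads, by microRNA reads and within the same length, and 10 by 18 to 22 nt reads, which also brings more families past the minimum. By construction, the higher RPM minimum drops families and the 1.5-fold rule adds them. Among families called by total reads, scaling by the median reversed the log2 ratio of the polyploid to the mid-parent for miR169 (-0.30), miR393 (-0.21) and miR528 (-0.31), and that to the hybrid for miR164 (-0.14), miR390 (-0.066) and miR393 (-0.28), because the median shift was subtracted. Of families not called by total reads, 7 also changed sign against the mid-parent (miR156, miR166, miR167, miR390, miR827, miR1432 and tasiARF) and 6 against the hybrid (miR156, miR167, miR169, miR827, miR1432 and tasiARF). Under the other 3 scalings 6 or 7 did so against the mid-parent and 5 or 6 against the hybrid. With random tags of the same length as each family's tag, the percentile of the polyploid over the mid-parent was 99.3 for all families, 99.8 for development, 94.5 for copper, and 47.4 for immune receptors and kinases in place of 24.9.

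Stowaway reads over the mid-parent were 0.867 in the hybrid and 0.522 in the polyploid. They were 0.759 and 0.340 over tags of at least 3 reads and 0.819 and 0.351 with 24 nt reads only. With 24 nt reads as denominator the polyploid reversed to 1.31 and its ratio to the hybrid to 1.45, and with 24 nt reads per 24 nt reads these were 0.892 and, reversed, 1.04. CACTA reads were 1.12 and 0.190. They were 1.03 and 0.0317 over tags of at least 3 reads, where DD over BBAA reversed to 0.814, and 1.08 and 0.442 with 24 nt reads as denominator. With 24 nt reads per 24 nt reads they were 1.07 and 0.354, and with 24 nt reads only the polyploid was at 0.153.

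Reads of rRNA and tRNA were at 1.16 of the mid-parent in the hybrid and 1.94 in the polyploid. With 1 mismatch they were 1.12 and 1.99, and with plastid tRNA ends 1.12 and 4.94. With 20 to 25 nt reads the polyploid was at 1.56.

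The DD share of single-parent 24 nt reads was 37.3% in the hybrid and 36.1% in the polyploid. It was 41.6% and 39.4% over distinct tags, 38.8% and 37.2% with at least 2 reads in a parent, and 27.3% and 25.8% as deposited, where the BBAA parent is deeper by construction. The mix of 2 to 1 was at 41.6% over distinct tags and at 41.0% with at least 2 reads in a parent. With another thinning seed the hybrid was at 37.0%.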

Other observations

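Of the tests in this part, those of the separate sequencing run, of the parental origin, of CACTA reads within the 24 nt class and of distinct CACTA tags were chosen only after the result was seen, and CACTA was taken up after its values were seen.

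The 24 nt share of the polyploid was 0.420 of the mid-parent. Dilution by a few abundant tags was argued against as the whole cause but not as a part of it, since without the 100 most abundant tags of each library the ratio rose to 0.630, and over distinct tags to 0.789, both under the 0.9 that this explanation needs. Loss of longer RNA during size selection stays open and met its test, for which 0.5 or less had been set as the mark. The ratio of 24 nt to 21 nt reads of rRNA and tRNA fragments was at 0.224 of the mid-parent (0.205 to 0.243). It was 0.242 for rRNA (0.219 to 0.267) and 0.102 for tRNA (0.0827 to 0.126), with 96 tRNA reads of 24 nt in the polyploid. The 5′ end of tRNA-Arg was at 8.43 of the mid-parent and that of tRNA-Ala at 1.27. The test thus cannot separate a loss of longer RNA from a change in which fragments were present. A separate sequencing run cannot be told apart from the group, because the polyploid alone had 0.584% of reads with an undetermined base, against at most 0.0242% elsewhere. A change caused by the doubled genome stays open and untested.

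CACTA reads of the polyploid were at 0.190 of the mid-parent. The shift to shorter reads was argued against as the whole cause, since per 1000000 reads of 24 nt the ratio was 0.354 (0.334 to 0.376), as were sequencing errors, with 0.348 when 1 mismatch was allowed (0.330 to 0.367). A few abundant tags in the other libraries were argued against by distinct tags at equal depth, 1029 in the polyploid against 1989, 2564 and 2683 in the BBAA parent, DD parent and hybrid, or 0.452 of the mid-parent. Within 21, 22 and 23 nt reads the ratio was 0.377, 0.389 and 0.417, and Stowaway reads were lower at 21 nt (0.638, 0.560 to 0.726), 22 nt (0.708, 0.532 to 0.941) and 24 nt (0.892) but not at 23 nt (1.03). The separate handling of this library cannot be told apart from the group, and less CACTA-derived RNA in the polyploid is a hypothesis that these 4 libraries leave untested.

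If 24 nt reads followed genome number, the DD share of the hybrid's single-parent reads would lie nearer to the mix of 2 to 1 (38.5%) than to the mix of 1 to 1 (53.8%), and at 37.3% (37.1 to 37.6) it did. It still lay below the interval of the mix of 2 to 1 (38.3 to 38.7). Over distinct tags, however, the hybrid (41.57%) and the mix of 2 to 1 (41.61%) were alike. Abundant DD-specific tags were at 25.8% of their parental level per 24 nt read (25.5 to 26.2) against 33.3% of the genomes. Tags of other organisms in the DD library were not left out and would lower this level. These marks take every genome to yield the same number of 24 nt reads, which was not tested. The 24 nt share of reads was 64.6% in the BBAA parent and 48.4% in the DD parent, so the gaps may depend on it. With 1 library per group these gaps cannot be set against a spread between plants.

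Some values belong to no comparison. Adenine was the first base of 52.7% of 24 nt reads in the BBAA parent, 60.8% in the DD parent, 61.3% in the hybrid and 56.1% in the polyploid. The number of distinct tags per 24 nt read was 0.628, 0.667, 0.668 and 0.817 in the same order. It was taken without thinning, over 3896185, 1510230, 3035159 and 639446 reads of 24 nt. Such a number falls with depth, so these values do not compare the diversity of the libraries. Reads 1 base from the main miR168 tag by an A-to-C change came to 0.673%, 1.07%, 0.604% and 4.92% of the exact reads. The 5′ end of tRNA-Arg was 8.43 times as high in the polyploid as in the mid-parent (8.07 to 8.81), and that of tRNA-Ala was 1.27 times as high (1.25 to 1.30).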
